A study of Mus musculus with 2 samples.

How the data were processed

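Mouse embryonic stem cells of the line ES-E14TG2a (129/Ola background), carrying a Dux transgene that doxycycline switches on, were profiled by droplet single-cell RNA sequencing on the 10x Chromium platform. Dux is a transcription factor that, when expressed, moves embryonic stem cells into a state resembling the mouse embryo at the 2-cell stage (2C-like). Per the labels' protocols, 2C-like cells were sorted and kept in culture for 24 h. There were 2 libraries, 1 collected at 0 h and 1 at 24 h, so no replicate exists and no test, p-value, standard error or standard deviation between libraries was computed.

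The deposited files of each library are a gene matrix and a matrix of repeat families over all 737280 barcodes of the kit. The gene matrices hold UMI counts (unique molecular identifiers, which mark single captured molecules) made by the authors with Cell Ranger, per the submitters' processing notes, and software version 3.0.2 stands in the matrix headers per the file headers. The submitters' processing notes list the builds mm10 and GRCm38 and Seurat 3. The repeat matrices hold whole-number counts per repeat family deposited by the authors, and how they were made, and whether they are UMIs or reads, is not given in the sources used here. A deposited table of counts joins 19918 genes and repeat families for the cells the authors kept. A deposited annotation gives each of 2298 cells a time and 1 of 3 classes, Exit_1, Exit_2 and Exit_3. How the authors filtered cells and made the classes is not given in the sources used here. A table of normalized values was not used here.

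The joined table lacks genes of the matrices, among them the mitochondrially encoded genes and the Rps genes, and all absent genes together hold 23.6% of the UMIs of the cells annotated 0 h and 18.2% of those annotated 24 h. Counts were therefore taken from the gene matrices, for the barcodes of the annotated cells. Each annotated cell was matched to a matrix by comparing its counts over 18925 genes and 968 repeat families. All 994 cells annotated 24 h were identical in every count to barcodes of the matrix filed under the 0 h sample, and all 1304 cells annotated 0 h to barcodes of the matrix filed under the 24 h sample. No cell matched the other way. Time was taken from the authors' cell annotation, so "the library annotated 0 h" and "the library annotated 24 h" are used throughout, and every direction over time rests on that choice. With the matrices as filed, every direction over time would be reversed.

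The matrices have 31053 genes, and those sharing a symbol were summed to 31017 symbols. Coordinates came from GENCODE vM21 (GRCm38) by gene identifier, found for 31011 identifiers. UMIs were summed over the cells of a library or class and converted to CPM of that sum. Each ratio has an exact 95% interval (conditional binomial, Clopper-Pearson). Sums have exact Poisson intervals and shares exact binomial ones, and medians of gene lists have intervals from Poisson redraws of the counts. All of these cover counting error only. Repeat counts were put on the same CPM scale, relative to the gene UMIs of the same cells. Where a gene had 0 counts in 1 group, its ratio was bounded with a floor of 3 counts summed over the group.

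These choices were made before the data were examined. A gene was measured with at least 50 UMIs over both groups compared. It was counted as higher or lower when its interval lay wholly at or beyond a 2-fold change. A member of a gene list was counted as higher or lower when its interval excluded no change and its ratio was at least 1.25-fold. The 25 gene lists cover 2C genes, 2C-associated genes of broader expression, naive and primed pluripotency, primitive endoderm, trophectoderm, mesoderm and germ layers, fibroblasts, nonsense-mediated decay, repressors of the 2C state, p53 targets, heat shock, the integrated stress and unfolded protein response, immediate early genes, glycolysis, cholesterol synthesis, DNA methylation, germline genes, ribosome biogenesis, translation, S phase, G2 and M phase, cytosolic ribosomal proteins, oxidative phosphorylation and mitochondrially encoded genes. The median log2 ratio of a list was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Named genes are the 10 highest and 10 lowest by ratio (5 each between classes) with at least 200 UMIs and an interval excluding 2-fold, without predicted genes (symbols of the Gm, Rik, BC, AC or AL kind), pseudogenes by name and mitochondrial genes, plus the 2 highest and 2 lowest members of each list, the Zscan4 genes, Duxf3 and a fixed set of repeat families. Some genes that the rule names are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

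Shares of cells with a UMI were computed after thinning each cell to 2000 UMIs, leaving out shallower cells. Barcodes with fewer than 50 UMIs served as a measure of free RNA, and UMIs per droplet in deep barcodes poor in 2C genes as an upper limit of it, the latter added after seeing the data. No doublet caller was run, and leaving out cells above the 95th percentile of UMIs was tried instead. The classes came from the authors' expression clustering, so the genes that separate them are description. They were set beside Leiden clusters of all annotated cells (resolution 0.5, 30 principal components of 2000 variable genes, 15 neighbours, both libraries without batch correction). The alternatives tried were TMM and median-of-ratios scaling, other UMI minimums, a set of cells made by a filter (at least 2000 UMIs, at least 1000 genes and at most 10% mitochondrial UMIs), means of per-cell shares, other thinning depths and clustering without the 2C genes. Assigning matrices as filed, keeping only annotated cells that pass the filter, other scalings of the class comparisons, other sets of cells for the germline and p53 lists, and leaving out single cells were added after seeing the data.

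The ratio and size rule were tested on simulated Poisson counts drawn from the means and depths of the real libraries, without spread between cells. For the comparison of the libraries, run on 9689 genes, it called 0% of genes changed 1.5-fold, 56.8% of those changed 3-fold, 78.0% of those changed 4-fold, and 0 of 9524 unchanged genes, and 95.7% of the intervals of unchanged genes held the true value. The intervals assume this same model, so the simulation checks the calculation and not the effect of uneven cells. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, the last for the TMM factors only.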

Results

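The data are UMI counts of genes and counts of repeat families in single mouse embryonic stem cells taken right after sorting for the 2C-like state (0 h) and after 24 h in culture, 1 library each. The question the design poses is which transcripts change as cells leave the 2C-like state for pluripotency. The authors annotated 1304 cells as 0 h and 994 as 24 h, but the matrix filed under each time holds the cells annotated with the other time. Time here follows the cell annotation, and every direction between the libraries would turn around if the filing were right. The cells annotated 0 h held 4006011 UMIs in total, with a median of 1584.5 per cell (range 79 to 41301) and a median of 429.5 genes. Those annotated 24 h held 17902593 UMIs, with a median of 18591.5 per cell (range 395 to 54288) and a median of 3623.5 genes. UMIs were more concentrated at 0 h, where the 10 most abundant genes took 22.8% of all UMIs, against 9.19% at 24 h.

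Genes of the 2C programme, which mouse embryos transcribe when their own genome is first activated, were far lower in the library annotated 24 h, and pluripotency genes were higher. All 36 measured 2C genes were lower, with a median log2 ratio of -5.11 (interval -5.13 to -4.95), and together they went from 65709 to 2012 CPM. Zscan4d (ENSMUSG00000090714, GRCm38 chromosome 7, 11161374 to 11166159), a zinc finger gene used as a marker of the 2C-like state, went from 5358 to 146 CPM, a log2 ratio of -5.20 (-5.26 to -5.14). Zscan4c (ENSMUSG00000054272, chromosome 7, 11005745 to 11010547) went from 2978 to 83.1 CPM, a log2 ratio of -5.16 (-5.24 to -5.09). Means of per-cell shares, which weigh shallow and deep cells alike, gave a smaller median of -2.87. These directions held under both other scalings, and with the matrices taken as filed all of them would be reversed.

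The other Zscan4 genes had log2 ratios of -5.17 (Zscan4b), -5.38 (Zscan4e) and -5.33 (Zscan4f), and how their near-identical copies share UMIs is uncertain. The same holds for Tcstv3 (chromosome 13, 120316878 to 120318178), at -5.65 with 7074 UMIs at 0 h and 629 at 24 h, for AF067063 (chromosome 13, 119827961 to 119830216) at -6.35, Gm4340 at -6.11, D13Ertd608e at -6.30, Gm2016 at -3.55 and Usp17la at -4.03. Duxf3 (ENSMUSG00000075046, chromosome 10, 58229979 to 58232675), the mouse Dux gene, stood at -4.23 (-4.54 to -3.93), and its counts may include the transgene. Outside the 2C list, the lowest ratios belonged to Spdye4b (chromosome 5, 143181017 to 143205075) at -6.44 (-7.04 to -5.89), with 544 and 28 UMIs. Clec10a (chromosome 11, 70156197 to 70170834), a lectin gene of macrophages and dendritic cells, had a ratio of -5.99 (-6.73 to -5.34). Tc2n at -5.81, Zfp287 at -5.70, Phf11a at -5.66, Fam186b at -5.52 and Pclo at -5.48 completed the 10 lowest under the naming rule. Among 12 genes associated with the 2C state but expressed more broadly, 11 were lower and 1 higher, with a median of -3.28 at percentile 0 of random lists of matched expression. Sp110 and Ubtfl1 were at -5.09 and -4.98, while Rbm25 and Plk2 were at -0.38 and -0.40.

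Of 38 measured genes of naive pluripotency, the ground state of the inner cell mass, 34 were higher in the library annotated 24 h and 2 lower, with a median log2 ratio of 2.18 (2.01 to 2.28). Their sum went from 6746 to 14978 CPM. Sox2 (ENSMUSG00000074637, chromosome 3, 34650405 to 34652461), a core pluripotency transcription factor, went from 17.0 to 230 CPM, a ratio of 3.76 (3.41 to 4.13). Utf1 (ENSMUSG00000047751, chromosome 7, 139943789 to 139945112), a chromatin-bound factor of pluripotent cells, went from 34.4 to 521 CPM, a ratio of 3.92 (3.68 to 4.17). Pou5f1 and Nanog, named after their values were seen, had ratios of 1.92 and 1.48. The 2 lower members were Fbxo15, from 952 to 118 CPM and -3.02 (-3.09 to -2.94), and Dppa2, a factor upstream of Dux, from 433 to 186 CPM and -1.22 (-1.31 to -1.14).

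The 10 highest ratios all belonged to genes with 1 or 2 UMIs at 0 h, so their intervals are wide. Sall3 (chromosome 18, 80966376 to 80986771), a zinc finger gene of the Spalt family, had 1 and 418 UMIs and a ratio of 6.55 (4.06 to 11.85). Gbx2 (chromosome 1, 89927956 to 89931179), a homeobox gene that sustains embryonic stem cell self-renewal, had 2 and 346 UMIs and a ratio of 5.27 (3.41 to 8.33). Among the others were Gpr160 at 5.73, Plekhg5 at 5.58, Zmat4 at 5.56, Icosl at 5.52, Nespas at 5.46, Mirg at 5.22 and Wsb2 at 5.20. Nespas lies antisense to Nesp, and UMIs of overlapping genes may be shared.

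Over all 10062 measured genes, 3877 were higher and 713 lower at 24 h by more than counting error beyond 2-fold, a split of 84.5% higher, and the median log2 ratio of all genes was 1.38. This split depends on the scaling. TMM gave 610 higher and 1127 lower (35.1% higher), and median-of-ratios gave 326 and 1398 (18.9%). Barcodes chosen by a filter on depth, genes and mitochondrial share gave 883 and 453 (66.1%), and the annotated cells passing that filter gave 1835 and 509 (78.3%). The filter kept 12.2% of the cells annotated 0 h and 87.5% of those annotated 24 h, and 42 of the 201 barcodes it kept from the former library have no annotation. Every log2 ratio fell by 1.09 under TMM. A gene or list just above 0 therefore turns negative there, and lists are given below with their percentile among random lists of matched expression.

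Naive pluripotency lay 0.80 above the median of all genes, with 25 of 38 higher and 9 lower relative to it, and above all of 10000 random lists of matched expression, while the 2C list lay at percentile 0. Other lists above the median of all genes kept their direction under both other scalings. This follows from the construction of these scalings, which lower every ratio by less than that median. Trophectoderm markers, which name the outer lineage of the blastocyst, had a median of 2.16 (9 of 9 higher, 4 higher and 0 lower relative to all genes, 0.78 above that median, percentile 90.3), with Tfap2c at 2.91, Krt18 at 2.83 and Krt8 at 1.76. Primed pluripotency genes had 2.08 (8 of 10 higher, 5 higher and 3 lower relative to all genes, 0.70 above, percentile 93.8), with Sox4 at 3.005 and Dnmt3b at 2.40, while Cd24a at 0.96 and Dnmt3a at 1.05 turn negative under both scalings. Primitive endoderm markers had 1.64 (8 of 9 higher, 0.27 above), at percentile 60.02 and with 3 of 9 higher and 1 lower relative to all genes, with Lama1 at 2.39, Sparc at 1.64 and Lamb1 at 0.34 (-0.20 to 0.92). Of the trophectoderm genes named, Krt18 had 121 of its 318 UMIs at 24 h in 1 cell, and its ratio was 2.14 without it. Tfap2c had 6 UMIs at 0 h, 3 of them in 1 cell, and its ratio was 3.89 without that cell.

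Repressors of the 2C state, mostly chromatin factors, are genes whose loss is known to release 2C genes. They had a median of 1.77, with 30 of 31 higher, 1 lower, and percentile 99.9. The list lay 0.39 above the median of all genes, with 13 higher and 7 lower relative to it. Mga, a subunit of a Polycomb complex, was at 3.96 (3.23 to 4.80) and the RNA-binding gene Lin28a at 3.06, while the deacetylase gene Hdac1 was at -0.71 and Rbbp4, which turns negative under both other scalings, at 0.57. All 8 genes of DNA methylation were higher (median 1.77, 0.39 above the median of all genes, 4 higher and 1 lower relative to it, percentile 93.6), including the demethylating enzyme gene Tet2 at 3.33 and Uhrf1 at 0.84, the latter turning negative under both other scalings. These lists share members and are not independent. Tet1, Tet2 and Dnmt3l are also in the naive list, Dnmt3a and Dnmt3b in the primed list, and Dnmt1 and Uhrf1 among the repressors. Lin28a and Zfp42 are in both the naive list and the repressors. Targets of the tumour suppressor p53 had a median of 1.70, with 16 of 19 higher, 2 lower and percentile 94.7. It lay 0.32 above the median of all genes, with 8 higher and 4 lower relative to it. The apoptosis gene Bbc3 (3 and 228 UMIs) was at 4.09 (2.52 to 6.38) and Phlda3 at 3.20, against -2.47 for Ddit4l and -1.19 for Pmaip1.

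Most remaining lists had a positive median that turned negative under another scaling. Nonsense-mediated decay, the pathway that removes transcripts with early stop codons, had a median of 1.247 (20 of 22 higher, 1 lower, percentile 48.9), which was 0.16 under TMM and -0.12 under median-of-ratios. Casc3 was at 2.70, while Eif4a3 was at -1.23 and Magoh at 0.54, the latter negative under both other scalings. Mesoderm and germ layer genes had 1.30 (3 of 4 higher, 1 lower, percentile 31.1), genes of the integrated stress and unfolded protein response 1.17 (10 of 14 higher, 3 lower, percentile 45.25) and S phase genes 1.09 (31 of 37 higher, 5 lower, percentile 34.9), each negative under median-of-ratios. Single members were Tubb3 at 1.11, which turns negative under median-of-ratios, and Snai1 at -3.16, Xbp1 at 3.94 (3 UMIs at 0 h), Chac1 at 3.16, Asns at -1.07 and Dnajb9 at -2.10, E2f8 at 2.91 and Pola1 at -1.29. Fibroblast markers (1.05, 3 of 4 higher), nuclear genes of oxidative phosphorylation (0.97, 67 of 79 higher, 3 lower), ribosome biogenesis (0.96, 18 of 22 higher, 1 lower), G2 and M phase (0.93, 35 of 48 higher, 4 lower) and immediate early genes (0.89, 4 of 8 higher, 1 lower) turned negative under both other scalings. Their percentiles among matched lists were 40.65, 74.7, 49.45, 15.2 and 6.28 in that order. Relative to the median of all genes, the members higher and lower were 4 and 5 for nonsense-mediated decay, 0 and 1 for mesoderm, 5 and 6 for the stress response and 5 and 17 for S phase. They were 1 and 2 for fibroblast markers, 5 and 43 for oxidative phosphorylation, 5 and 11 for ribosome biogenesis, 8 and 28 for G2 and M phase and 2 and 3 for immediate early genes. Their members reached from -1.88 (Cenpf) and -1.78 (Nip7) to 2.97 (Cald1), 2.57 (Tmpo), 2.33 (Gar1), 2.15 (Ier2) and 2.07 (Atp5g1).

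A further group had medians from 0.11 to 0.71, which all turned negative under TMM and median-of-ratios. It held translation factors (0.71, 16 of 22 higher, 3 lower), germline genes (0.59, 7 of 13 higher, 3 lower), heat shock genes (0.38, 7 of 12 higher, 3 lower), cholesterol synthesis (0.26, interval -0.01 to 0.48, 7 of 16 higher, 5 lower), glycolysis (0.21, 8 of 17 higher, 0 lower) and cytosolic ribosomal proteins (0.11, 19 of 82 higher, 10 lower). Translation factors stood at percentile 52.5 of lists matched on expression and heat shock genes at 11.6, while germline genes, glycolysis, cholesterol synthesis and ribosomal proteins stood at 1.745, 2.30, 0.12 and 0.10. Relative to all genes 3 translation factors were higher and 16 lower, against 1 and 9 for heat shock, 2 and 7 for germline genes, 1 and 13 for glycolysis and 0 and 12 for cholesterol synthesis. Ribosomal proteins had a median of -1.26 relative to all genes, with 80 of 82 members lower on that scale. Members at the ends were Eif4ebp1 at 2.25 and Eif4a2 at -1.21, Mael at 1.97 and Dazl at -1.15, Hspe1 at 2.05 and Hspa1a at -2.64, Hk2 at 2.31 and Gapdh at -0.29, and Dhcr7 at -2.93. Rps27l was at 1.81 and Rps29 at -1.10, where UMIs of ribosomal pseudogenes may be shared. Mitochondrially encoded genes were lower under every scaling, with 12 of 13 lower and 1 higher, a median of -1.47 at percentile 0.11, and a sum going from 100785 to 43218 CPM. The lowest was mt-Atp8 at -2.40, and mt-Nd1 at 0.45 was the higher one, turning negative under TMM and median-of-ratios.

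**Figure D1:**
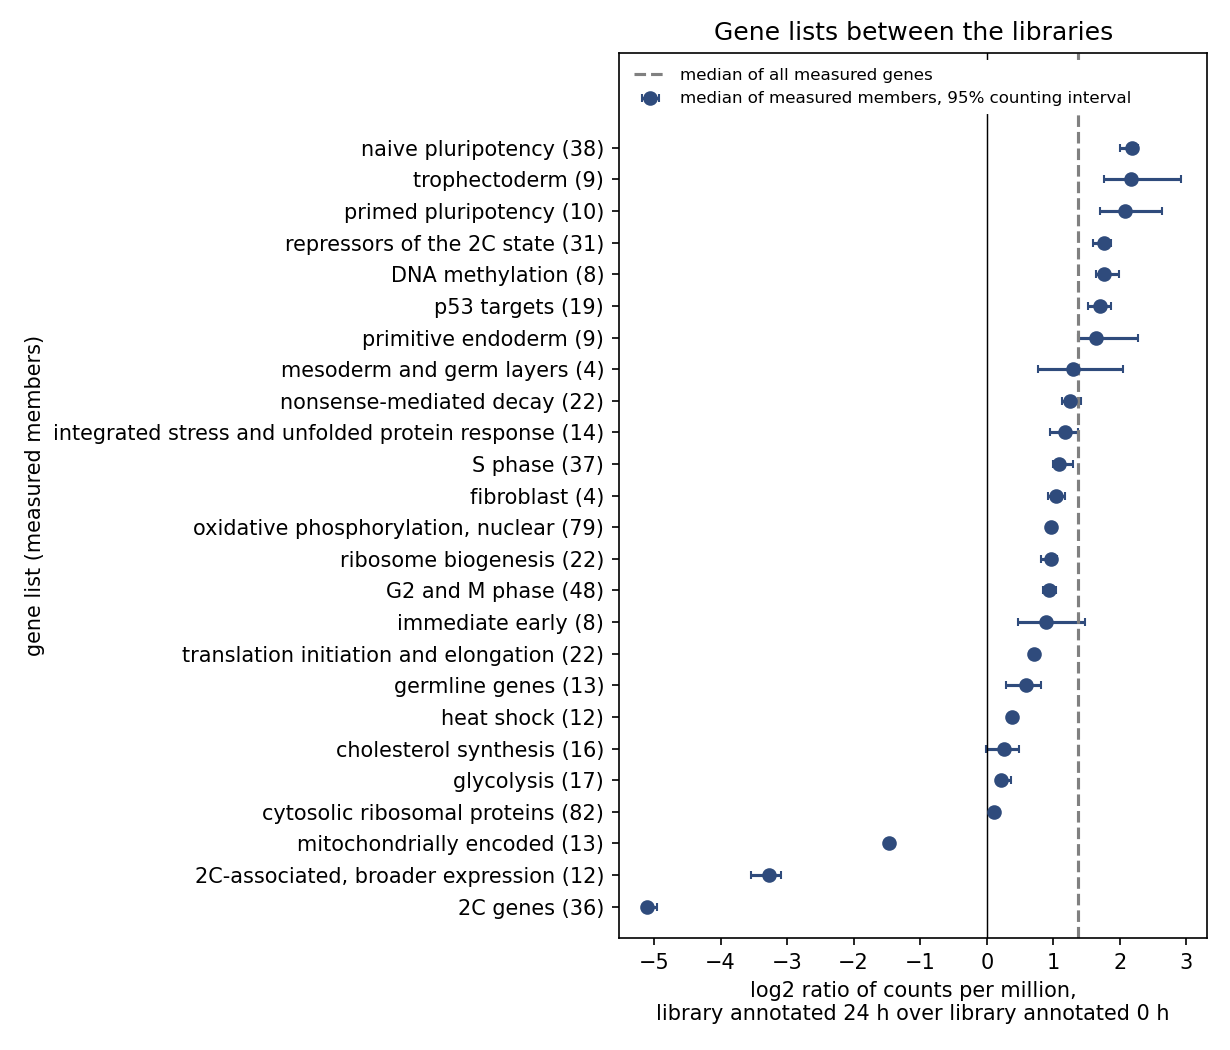
Median log2 ratio of CPM, library annotated 24 h over library annotated 0 h, for 25 gene lists (measured members in brackets), with bars for the 95% counting interval and a dashed line at the median of all measured genes (1.38). The 2C list lies lowest at -5.11 and naive pluripotency highest at 2.18; lists between 0 and 1.05 turn negative under TMM and those from 0 to 1.30 under median-of-ratios scaling.

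The retroviral repeats MERVL-int and MT2_Mm were lower together with the 2C genes. MERVL-int, the internal part of an endogenous retrovirus expressed in 2-cell embryos, fell by 4.90 on the log2 scale per gene UMI in the library annotated 24 h (-4.94 to -4.86), and its promoter repeat MT2_Mm had -4.94 (-4.96 to -4.91). The intervals treat every repeat count as independent. If the counts are reads, which is not known, the intervals are too narrow and ratios per gene UMI set reads against UMIs. MERVL-int and MT2_Mm were also lower per repeat count, at -1.05 and -1.09, and per cell, at -2.35 and -2.38. Of 589 measured families 475 were lower and 41 higher per gene UMI by intervals that excluded no change, with a median of -1.76. Per repeat count, where families were counted by sign alone without an interval, 62 were lower and 527 higher. Total repeat counts per gene UMI were 2.20 at 0 h and 0.153 at 24 h. Per gene UMI, GSAT_MM, the mouse major satellite, had -5.21, ORR1A0 -3.12, B1_Mm -3.02, MT2A -2.38, IAPEz-int -1.83, IAPLTR1_Mm -1.59, MT2B -1.23, MMERGLN-int -1.20, L1Md_A -1.04, L1Md_T -0.92, RLTR45-int -0.22, L1Md_Gf -0.12 and ETnERV-int 0.94. GSAT_MM stayed lower per repeat count, while all the others from ORR1A0 (0.72) to L1Md_Gf turned positive on that scale. In the filed order of the matrices all of these signs would be reversed.

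Zscan4 UMIs were found in most droplets of the library annotated 0 h and in a minority of that annotated 24 h. After thinning to 2000 UMIs per cell, 96.5% of 549 cells at 0 h had a UMI of a Zscan4 gene (94.6% to 97.9%), against 11.4% of 945 cells at 24 h (9.47% to 13.6%). Thinning left out 755 and 49 shallower cells, and the median depths of the others were 4433 and 18847 UMIs. Without thinning the shares were 89.6% and 20.7%. No background was subtracted from these shares. Barcodes with fewer than 50 UMIs held 6234 and 479 CPM of Zscan4 genes, and 2000 UMIs of such free RNA alone would include a Zscan4 UMI in nearly all cases at 0 h and in 61.7% at 24 h. Free RNA adds to every droplet, so a comparison without thinning was added after these values were seen. In the library annotated 0 h, 42 barcodes that passed the depth filter without an annotation (median 24391 UMIs) had a Zscan4 UMI in 40.5% of cases (25.6% to 56.7%), against 89.6% of Exit_1 cells (87.8% to 91.2%). After thinning, fibroblast markers gave 1.28% and 2.12%, and primitive endoderm markers 2.73% and 6.35%. Any gene of the 2C list was seen in 99.3% and 17.8% of cells, and MERVL-int in 96.6% of 965 and 35.2% of 580 cells thinned to 2000 repeat counts. At 24 h, 82.2% of cells had 0 UMIs of the 2C list in 2000 and 8.68% had 30 or more, while at 0 h 95.6% had 30 or more.

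The authors' classes split along the same line. Exit_1 held 1271 of the cells annotated 0 h (97.5%, 96.5% to 98.3%), Exit_2 held 9 (0.690%) and Exit_3 held 24 (1.84%). Among the cells annotated 24 h, Exit_1 held 126 (12.7%, 10.7% to 14.9%), Exit_2 held 92 (9.26%, 7.53% to 11.2%) and Exit_3 held 776 (78.1%, 75.4% to 80.6%). The classes came from expression, so genes that separate them are description. Leiden clusters of the same cells placed 96.3% in their class, but Exit_2 was matched less well. The cluster led by Exit_2 had 95 cells, 68 of Exit_2, 13 of Exit_1 and 14 of Exit_3, and 31 Exit_2 cells fell in the cluster led by Exit_3. Clustering without the 2C genes placed 94.0% of all cells in their class, with no cluster led by Exit_2, and gave 24 h shares of 16.7%, 0% and 83.3%. Depth differed between classes at 24 h, with median UMIs of 2534 in Exit_1, 17244 in Exit_2 and 19666.5 in Exit_3.

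**Figure D2:**
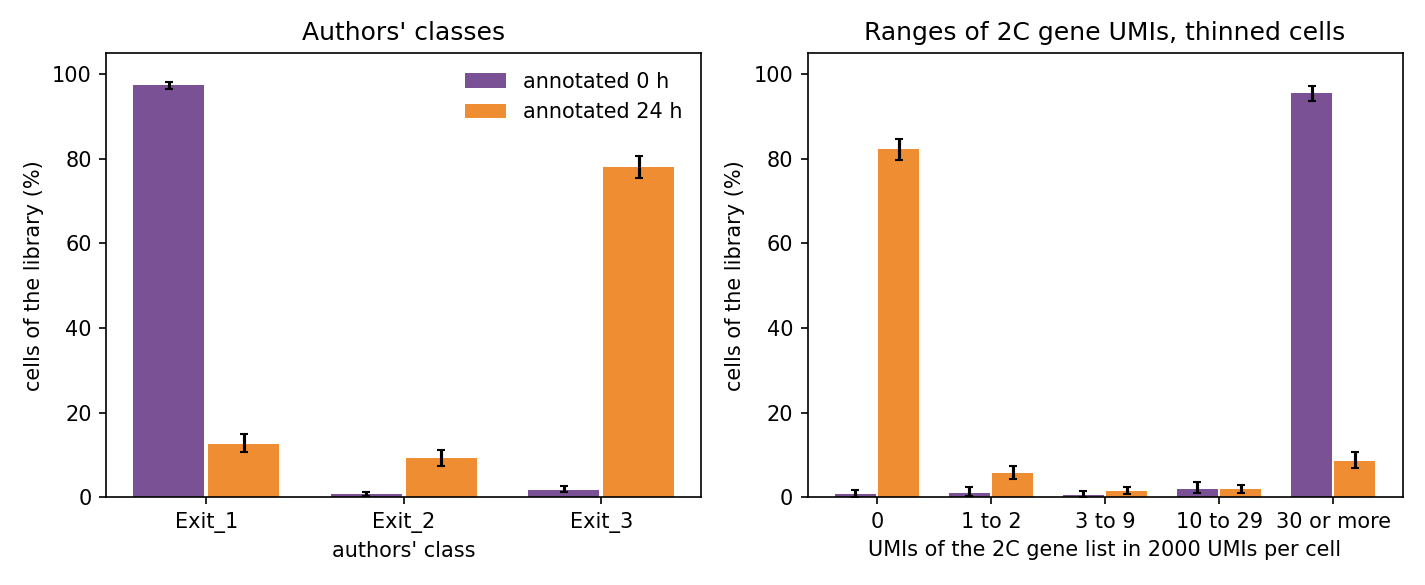
Percent of cells per library, left by the authors' class (1304 and 994 cells) and right by the number of UMIs of the 2C list in 2000 UMIs per cell (549 and 945 cells), with exact 95% binomial bars. Exit_1 holds 97.5% of the cells annotated 0 h and Exit_3 78.1% of those annotated 24 h, and the range of 30 or more 2C UMIs holds 95.6% and 8.68%.

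Within the library annotated 24 h, where comparisons between classes do not rest on the time labels, Exit_2 cells had far fewer 2C transcripts than Exit_1 cells and more of the pluripotency programme. All 24 measured 2C genes were lower, with a median log2 ratio of -4.28 (-4.38 to -4.02), and the list summed to 59156 CPM in Exit_1 and 3655 CPM in Exit_2, while barcodes with fewer than 50 UMIs, a measure of free RNA, held 4811 CPM. Exit_2 cells were uneven, with a mean of 64.2 and a median of 9 UMIs of the list per cell. Among 91 of them thinned to 2000 UMIs, 38 had 0, 21 had 1 to 2, 10 had 3 to 9, 11 had 10 to 29 and 11 had 30 or more. All 8 broader 2C-associated genes were lower too (median -3.08). Of 35 naive pluripotency genes 31 were higher and 1 lower, with a median of 1.38, and 0.68 under TMM. The 5 highest genes under the naming rule included Tbx3 (chromosome 5, 119670669 to 119684724), a T-box factor that supports self-renewal, at 3.21 (2.26 to 4.35) with 9 and 272 UMIs, and Sox2 at 2.95 (2.21 to 3.80). The others were Ubtf, Kcnq1ot1 and Igfbp2 at 3.08, 2.93 and 2.71.

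The lowest genes of Exit_2 against Exit_1 under the naming rule were Tcstv3 at -9.97 (-13.02 to -8.11), with 611 and 2 UMIs, and AF067061 at -7.997, both with near-identical copies, then Tmem267 at -6.44, Loxl2 (chromosome 14, 69609068 to 69695834), a lysyl oxidase gene, at -6.33 (-7.00 to -5.73), and Sp110 at -5.91. Duxf3, Zscan4d and Zscan4c had -5.34, -4.12 and -3.77. Repressors of the 2C state had a median of 1.14, with 20 of 25 higher, 0 lower and 0.44 under TMM. Among them Max was at 1.91 and the heterochromatin gene Cbx5 at 1.90, against -0.06 for Hdac1. Nonsense-mediated decay genes had a median of 1.07 (11 of 15 higher, 1 lower, percentile 82.1) and germline genes 1.01 (4 of 7 higher, percentile 48.2). These were 0.37 and 0.31 under TMM. Mitochondrially encoded genes had -0.91, with 10 of 11 lower, led by mt-Nd5 at -2.14. The medians of p53 targets (0.36, with Aen at 1.39 and Ddit4l at -1.90), of the stress response list (0.14) and of cytosolic ribosomal proteins (0.09) turned to -0.33, -0.56 and -0.60 under TMM. Of 3930 measured genes 276 were higher and 243 lower (53.2% higher), but TMM gave 26 and 299 (8%) and median-of-ratios 20 and 317 (5.93%), and the median of all genes was 0.84.

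Exit_3 cells annotated 24 h had fewer of the remaining 2C transcripts and of germline transcripts than Exit_2 cells, while the median of the naive pluripotency list lay near 0. All 16 measured 2C genes were lower, with a median of -5.96 (-6.21 to -5.71), and the list summed to 59.5 CPM in Exit_3, with most of its UMIs in 5 of the 776 cells. Zscan4c stood at -6.10 (-6.62 to -5.62) and Zscan4d at -6.02. Of 13 germline genes, which act in germ cells and are mostly silenced by DNA methylation elsewhere, 12 were lower, with a median of -1.54 (-1.64 to -1.05) at percentile 0 of matched lists, and -1.39 under TMM. Dazl (chromosome 17, 50279395 to 50293636), an RNA-binding gene of germ cells, had 118 and 138 UMIs and a ratio of -3.06 (-3.43 to -2.70), and Mael was at -1.56.

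Naive pluripotency had a median of 0.02 from Exit_2 to Exit_3, with 11 of 38 higher and 10 lower. Within it Utf1 was at 1.42 (1.26 to 1.58) and Tet2 at 1.22, while Dppa3, a maternal factor of the early embryo, was at -3.02 (-3.34 to -2.69) and Fbxo15 at -2.35. Of the 149 Dppa3 UMIs in Exit_2, 109 lay in 1 cell, and without it the ratio was -1.15 (-1.65 to -0.62). Hmgn3 (chromosome 9, 83109948 to 83146685), a nucleosome-binding gene, was at -3.33 and Crxos (chromosome 7, 15882617 to 15904020), a homeobox gene, at -3.16 (-3.45 to -2.87). The highest were Wsb2 at 4.06 (2.20 to 7.12), Cpne5 at 3.53, Dapk1 at 3.32 and Galk2 at 3.27, each with 2 or 3 UMIs in Exit_2, and Catip at 3.17 (2.12 to 4.49). DNA methylation genes had a median of 0.26 (3 of 8 higher, 0 lower), S phase genes 0.11 (6 of 37 higher, 2 lower) and repressors of the 2C state -0.01 (0.14 under TMM), with Ehmt2, a histone methyltransferase gene, at 1.48 and Setdb1 at -0.78. G2 and M phase genes had -0.16, with 4 of 48 higher and 17 lower, and -0.01 under TMM. Of 9475 measured genes 131 were higher and 191 lower (40.7% higher), TMM gave 187 and 157 (54.4%), and the median of all genes was -0.01.

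Exit_3 cells annotated 24 h differed most from Exit_1 cells in their 2C genes. All 23 measured 2C genes were lower (median -9.87), with Zscan4d at -10.14, Zscan4c at -9.87, Tcstv3 at -10.26, AF067061 at -10.65 and Sp110 at -9.98. Naive pluripotency had a median of 1.46, with 30 of 38 higher and 3 lower, including Sox2 at 2.95 (2.23 to 3.79), Tet1 at 2.90 and Fbxo15 at -3.02. The highest gene was Epha4, an ephrin receptor gene, at 4.79 (2.31 to 10.10) with 1 and 887 UMIs, followed by Carnmt1 at 4.74, Spop at 4.54, Plekha4 at 4.52 and Socs2 at 4.52. Of 9365 measured genes 601 were higher and 364 lower (62.3% higher), but TMM gave 139 and 474 (22.7%) and median-of-ratios 50 and 590 (7.81%), and the median of all genes was 0.76.

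**Figure D3:**
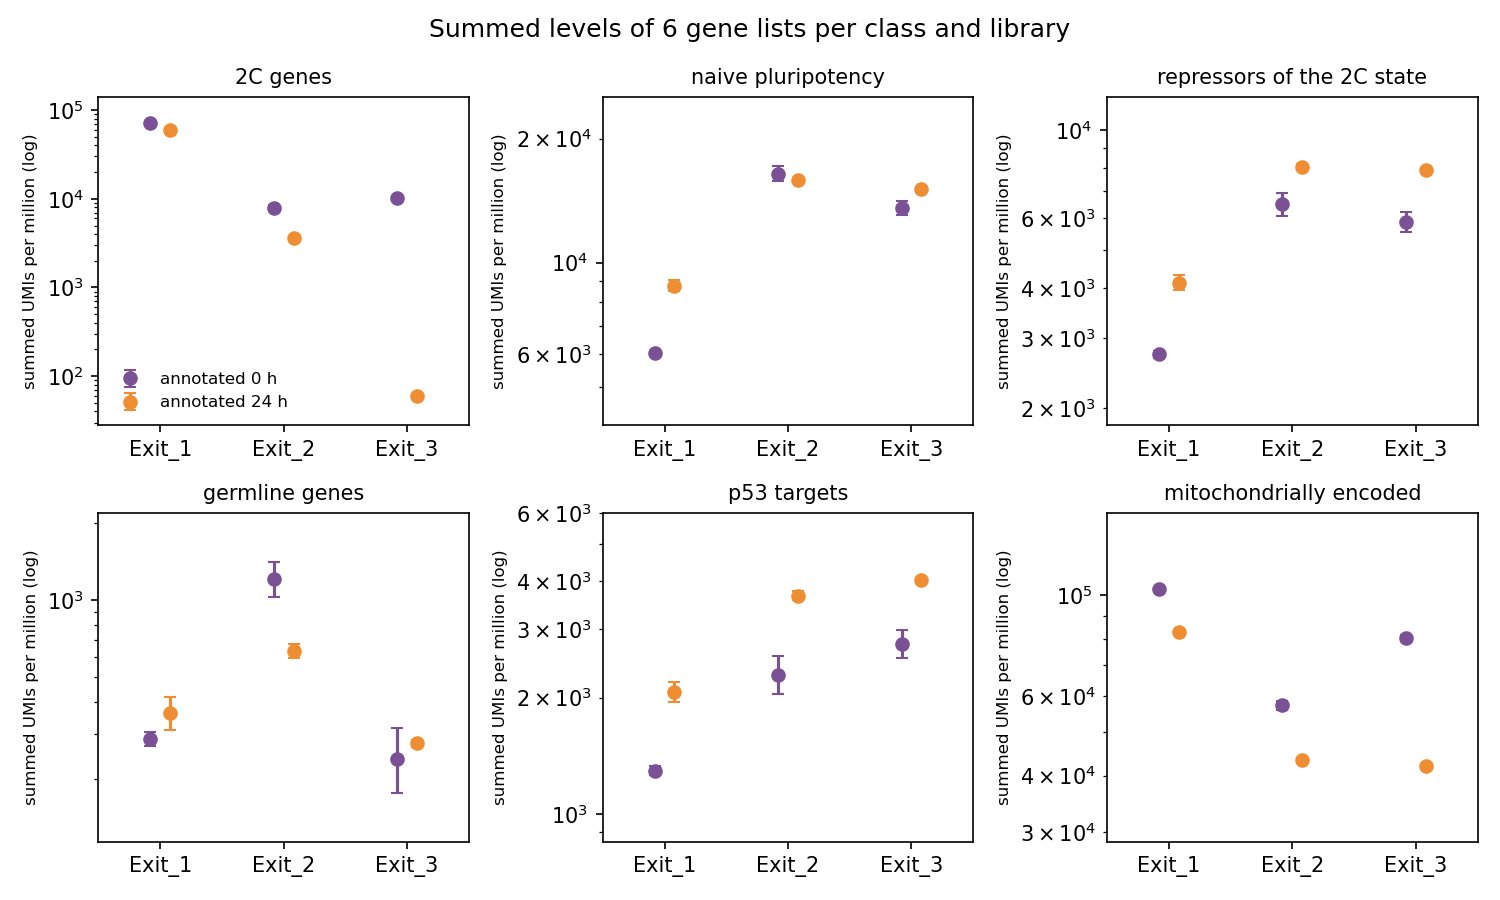
Summed CPM (log axes) of 6 gene lists in the authors' classes of each library, with 95% Poisson bars; the 0 h points of Exit_2 and Exit_3 rest on 9 and 24 cells. At 24 h the 2C list goes from 59156 in Exit_1 to 3655 in Exit_2 and 59.5 in Exit_3, and germline genes from 363 to 635 and 277.

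Pooled over cells, Exit_1 annotated 24 h against Exit_1 annotated 0 h had a lower median ratio of 2C genes than all matched lists. It also had more transcripts of p53 targets. The 2C list summed to 70859 CPM at 0 h and 59156 CPM at 24 h, with a median ratio of -0.32 (-0.35 to -0.17), 6 of 36 genes higher and 14 lower, and -0.96 under TMM. It stood at percentile 0 of matched lists, with 0 higher and 25 lower relative to all genes. Over resampled cells the sums had intervals of 66718 to 75283 and 49696 to 70418 CPM. These intervals overlap, and the median per cell went the other way, from 53914 CPM at 0 h to 58936 CPM at 24 h. The pooled values therefore do not show a fall in the typical Exit_1 cell. Barcodes with fewer than 50 UMIs of the library annotated 0 h held 55252 CPM of the same genes, close to its Exit_1 cells. Zscan4c and Zscan4d were at -0.44 and -0.41, and Duxf3, which may include the transgene, was at 0.67 and near 0 once scaled by TMM. Of 11 p53 targets 10 were higher and 0 lower, with a median of 1.01 (0.79 to 1.23) at percentile 99.9, and 0.37 under TMM. Among them were Ccng1 at 1.28 and the apoptosis gene Bax at 1.07, with Ddit4l at 0.12, negative under TMM. The p53 list summed to 1295 CPM in Exit_1 at 0 h, 2069 CPM in Exit_1 at 24 h and 4014 CPM in Exit_3 at 24 h. Naive pluripotency genes went through 6019.5, 8781 and 15078 CPM in the same order, but glycolysis genes through 6814, 6398 and 7924 CPM. Exit_3 RNA mixed into the shallow Exit_1 droplets at 24 h would raise the p53 and naive lists too, and this was not tested. Gadd45g (chromosome 13, 51846678 to 51848468), a growth arrest gene, had the highest ratio at 5.16 (4.63 to 5.73) with 35 and 168 UMIs, but 147 of the latter lay in 1 cell, and without it the ratio was 2.19 (1.34 to 3.02). Id3 at 2.53, the stress gene Ddit4 at 2.20, Hspa1a at 2.07 and Ifitm1 at 2.06 came next. For Hspa1a 72 of 136 UMIs at 24 h lay in 1 cell, and the ratio was 1.02 without it.

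Naive pluripotency genes had a median of 0.73 between the Exit_1 cells of both libraries, with 17 of 25 higher and 1 lower, and 0.09 under TMM. Heat shock genes (0.61, 7 of 12 higher, 0 lower) and repressors of the 2C state (0.56, 9 of 21 higher, 0 lower, with Rif1 at 1.49) turned to -0.04 and -0.08 under TMM. Mitochondrially encoded genes had -0.49, with 7 of 12 lower and 1 higher, the latter being mt-Nd1 at 0.68. The lowest genes were Rab11fip1 at -4.12 (-6.00 to -2.76), Hist1h2bj at -2.34, Tc2n at -2.29, Fbxw2 at -2.27 and Golga3 at -2.21. Of 3845 measured genes 64 were higher and 32 lower (66.7% higher), while TMM gave 11 and 168 (6.15%) and median-of-ratios 18 and 76 (19.15%), and the median of all genes was 0.35. These directions over time also rest on the cell annotation and would be reversed in the filed order.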

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

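The tests of technical explanations in this part, on mixed RNA, on free RNA, on a property of a whole library and on exchanged labels, were all chosen after the results they bear on had been seen. No biological explanation was tested, because the design has no group that would separate one from the time of collection.

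The first pattern is the 2C level of Exit_2 cells annotated 24 h, pooled at 3655 CPM (2124 to 5458 over resampled cells) between 59156 CPM in Exit_1 and 59.5 CPM in Exit_3, with a median per cell of 546 CPM and most of the UMIs in 7 of 92 cells. Germline genes summed to 635 CPM in Exit_2 (564 to 707 over resampled cells), above the 363 and 277 CPM of Exit_1 and Exit_3. Mixing RNA of those classes alone would not give a sum above both. The list was picked after its level in Exit_2 was seen, however. Of its 5 members measured in Exit_2, 1 was at least 2-fold higher than in both other classes. The germline median of Exit_2 over Exit_1 lay at percentile 48.2 of matched lists. The germline sum is therefore only weak evidence against a profile made wholly of mixed RNA. Among 91 genes at least 20-fold higher in Exit_1 than in Exit_3, 52.7% had an interval that left out the common mixing fraction of 3.58%, 24 above and 24 below, which argues against Exit_1 transcripts entering Exit_2 at a single fraction. Exit_2 cells had a mean of 2C UMIs 53.025 times that of Exit_3 cells (26.2 to 112). The classes came from expression, and clustering without the 2C genes gave no cluster led by Exit_2. The ratio may therefore in part follow from how the classes were made. Free RNA spread evenly over droplets would, however, give every droplet of the library about as many 2C UMIs. Most of those in Exit_2 lay in 7 of 92 cells, with 995 in 1 cell, against a mean of 1.21 in Exit_3 cells. This argues against evenly spread free RNA giving the summed level. Such RNA stays open for the 28.3% of Exit_2 cells that held no more than the Exit_3 mean of 1.21 UMIs. Unevenly spread RNA of another composition was not tested and stays open too.

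The second pattern is that Exit_1 cells held few genes and many repeat counts, with medians of 1515 UMIs at 0 h and 2534 at 24 h and with 2.36 and 1.61 repeat counts per gene UMI. A property of the whole library annotated 0 h is argued against by the library annotated 24 h, where Exit_1 had 14.7 times the repeat counts per gene UMI of Exit_3. Droplets with free RNA of the composition of low barcodes in place of a cell are argued against at 24 h. There the 2C level of Exit_1 was 12.3 times that of low barcodes. Exit_1 came from expression, so part of this ratio may follow from how the class was made. At 0 h, free RNA spread evenly over droplets is argued against by Exit_1 barcodes holding 21.3 times (11.3 to 68.6) the 2C UMIs per barcode of 42 deep barcodes without annotation, with means of 205 and 9.62 and medians of 75 and 3. By level, however, low barcodes at 0 h resembled Exit_1 cells. They held 55252 CPM of 2C genes against 70859 CPM, and 3.35 repeat counts per gene UMI against 2.36. Free RNA spread unevenly over droplets therefore stays open at 0 h. At 24 h, unevenly spread free RNA of another composition than that of the low barcodes was not tested and stays open. Damaged cells or fragments of cells in these droplets were not tested.

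The third pattern is the conflict between the cell annotation and the filing of the matrices. Exchanged matrices need the library annotated 0 h to be the richer in the 2C programme for which cells were sorted, and the 2C list was 32.7 times as high in its cells as in those annotated 24 h. An annotation with exchanged times needs the same of the cells annotated 24 h, but 17.8% of them had a UMI of the 2C list in 2000. A candidate explanation is therefore that the matrices were filed under each other's sample, which only the submitters can settle.

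Some contrasts between classes pointed in opposite directions in the libraries, and these differences were not tested, with 9 Exit_2 and 24 Exit_3 cells at 0 h. Cytosolic ribosomal proteins had a median log2 ratio of Exit_2 over Exit_1 of -0.11 at 0 h and 0.094 at 24 h, over 82 genes each. The 2C list had a ratio of Exit_3 over Exit_2 of 0.56 at 0 h (10 measured genes) and -5.96 at 24 h (16 genes). For S phase genes the same ratio was -0.67 (5 genes) and 0.11 (37 genes), and for mitochondrially encoded genes 0.33 (11 genes) and -0.081 (13 genes). Where these numbers differ, the medians rest on different members.

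A signal also stood in barcodes outside the annotation. In the library annotated 0 h, 42 barcodes without annotation passed the depth filter, with a median of 24391 UMIs, 389.97 CPM of 2C genes, 20139 CPM of naive pluripotency genes and 0.122 repeat counts per gene UMI. A Zscan4 UMI was seen in 17 of them. These barcodes are outside the class shares at 0 h, where Exit_2 and Exit_3 held 9 and 24 cells. The filtered set that holds them gave a smaller naive pluripotency median than the annotated cells passing the filter. Why they have no annotation is not known.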

How the results depend on the processing

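Of the alternatives below, the matrices as filed, the annotated cells passing the filter, both scalings of the class comparisons, the other sets of cells for germline genes and p53 targets, and the omission of single cells were added after seeing the data. Over 352 recomputed values, 139 moved by less than their counting interval or less than 1.5-fold for counts, 177 moved further and 36 whose interval excluded 0 reversed. Cholesterol synthesis, whose interval of -0.01 to 0.48 held 0, is counted among the 177 and turned to -0.83 under TMM, -1.11 under median-of-ratios, -0.67 in the cells chosen by the filter and -0.020 in the annotated cells passing it. The 2C list stayed lower and naive pluripotency higher under all alternatives except the filed order of the matrices. Depth limits the library annotated 0 h, where genes that rise start from few UMIs, and the 9 and 24 cells of Exit_2 and Exit_3 there. Reversals and kept directions under TMM and median-of-ratios follow from their construction, a common shift of all ratios. Reversals in the filed order follow from the exchange of the libraries. For the other values given here the cause was not tested.

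TMM gave 610 higher and 1127 lower genes, with medians of -6.20 for 2C genes, 1.09 for naive pluripotency and 0.16 for nonsense-mediated decay. Besides cholesterol synthesis, TMM reversed fibroblast markers (-0.044), heat shock (-0.71), immediate early genes (-0.20), glycolysis (-0.88), germline genes (-0.50), ribosome biogenesis (-0.13), translation (-0.38), G2 and M phase (-0.16), cytosolic ribosomal proteins (-0.97) and oxidative phosphorylation (-0.12). Median-of-ratios gave 326 higher and 1398 lower genes, -6.48 for 2C genes and 0.81 for naive pluripotency. Besides cholesterol synthesis, it reversed mesoderm (-0.073), fibroblast markers (-0.32), nonsense-mediated decay (-0.12), heat shock (-0.99), the stress response list (-0.20), immediate early genes (-0.48), glycolysis (-1.16), germline genes (-0.78), ribosome biogenesis (-0.41), translation (-0.66), S phase (-0.28), G2 and M phase (-0.44), cytosolic ribosomal proteins (-1.25) and oxidative phosphorylation (-0.40).

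In the class comparisons TMM left 26 genes higher in Exit_2 than in Exit_1, and 11 higher and 168 lower in Exit_1 at 24 h than at 0 h. Median-of-ratios left 20, 18 and 76. The germline median of Exit_3 over Exit_2 was -1.31 with the 38 Exit_2 cells that had no 2C UMI after thinning and -1.53 without cells above the 95th percentile of UMIs. The p53 median between Exit_1 cells was 0.99 in cells of at least 2000 UMIs. Leaving out the cell that held most UMIs of a named gene moved Gadd45g between the Exit_1 cells from 5.16 to 2.19 and Hspa1a there from 2.07 to 1.02, and Dppa3 of Exit_3 over Exit_2 from -3.02 to -1.15. Between the libraries it moved Hspa1a to -3.36, Krt18 to 2.14 and Zscan4f to -6.36. It also moved genes with few UMIs in 1 group, among them those with the highest ratios.

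Cells chosen by the depth filter gave 883 higher and 453 lower genes, -5.33 for 2C genes, 0.93 for naive pluripotency, 0.69 for nonsense-mediated decay, reversed heat shock (-0.12) and glycolysis (-0.74), -4.69 for MERVL-int and -4.61 for MT2_Mm. The Zscan4 shares there were 76.1% and 6.31%, and 71.6% and 3.33% of cells had 30 or more 2C UMIs. Annotated cells passing the filter gave 1835 higher genes, -5.97, 1.71 and 0.99 for the same lists, -5.33 for MERVL-int and -5.24 for MT2_Mm, and reversed heat shock (-0.048), glycolysis (-0.34), germline genes (-0.069) and cytosolic ribosomal proteins (-0.019). Means of per-cell shares gave -2.87 for 2C genes and 2.42 for naive pluripotency. Without cells above the 95th percentile of UMIs naive pluripotency had 2.64 and nonsense-mediated decay 1.64.

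A minimum of 500 UMIs left 1936 higher and 294 lower genes, and a minimum of 1 UMI gave 1100 lower genes and reversed fibroblast markers (-0.34). Leaving mitochondrially encoded genes out of the total moved 2C genes to -5.20. MERVL-int and MT2_Mm had -1.05 and -1.09 per repeat count and -2.35 and -2.38 per cell. In the filed order 713 genes were higher and 3877 lower, with 5.11 for 2C genes, -2.18 for naive pluripotency, -1.25 for nonsense-mediated decay, 4.90 for MERVL-int and 4.94 for MT2_Mm.

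Zscan4 shares without thinning were 89.6% and 20.7%. Thinning to 1000 UMIs gave 90.8% at 0 h, and thinning to 4000 UMIs gave 9.04% at 24 h, with 4.52% of cells in the top 2C range when its limits were doubled. Counting Zscan4 genes only, 19.9% and 1.38% of cells had 30 or more UMIs. Leiden clusters gave Exit_3 0.844% at 0 h. Clustering without the 2C genes gave shares of 99.1%, 0% and 0.920% at 0 h and 16.7%, 0% and 83.3% at 24 h.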

Other observations

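The gene groups and cells in this part were all chosen after their values were seen, and no explanation of them was tested.

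Exit_2 cells annotated 24 h held transcripts that peaked in that class. Of 3428 genes with at least 50 UMIs in Exit_2, 58 had a ratio of at least 2-fold over both other classes. Their intervals had to exclude no change only, a looser rule than the one used above. By the same rule 15 genes were lower than in both. These were counted over genes with at least 50 UMIs in all classes together, so the counts rest on different sets. Both counts depend on the scaling, with 18 higher and 42 lower under TMM and 19 and 44 under median-of-ratios. Crxos, Igfbp2 and Calcoco2 are among the higher ones under all of these. Crxos stood at 121 CPM in Exit_2 against 28.4 CPM in Exit_1 and 13.5 CPM in Exit_3. The maternal factor gene Dppa3 stood at 92.3 CPM against 6.08 (3 UMIs) and 11.4 CPM, but at 25.3 CPM without 1 cell that held 109 of its 149 UMIs. Igfbp2, which encodes a binding protein of insulin-like growth factors, stood at 212 CPM against 32.4 and 58.7 CPM. Calcoco2 stood at 357 CPM against 83.1 and 126 CPM.

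Cells annotated 24 h were also grouped by their UMIs of the 2C list in 2000, with levels given in CPM of all other genes. Dppa2, a factor upstream of Dux, went from 144 CPM in the 777 cells with 0 such UMIs to 269.8, 557, 785 and 915 CPM in the ranges 1 to 2, 3 to 9, 10 to 29 and 30 or more, which held 54, 14, 18 and 82 cells. Fbxo15 went from 79.5 to 212, 480, 472 and 816 CPM. Germline genes were highest in between, at 829 CPM in the range of 3 to 9, against 285 CPM at 0 and 557 CPM at 30 or more. The ranges of 3 to 9 and 10 to 29 hold fewer than 20 cells each. The cells annotated 0 h gave no such steady course. Their ranges held 4, 6, 3, 11 and 525 cells, and Dppa2 went through 93.1, 254, 1590 and 1496 to 495 CPM. In the same ranges Fbxo15 had 169, 155, 2020, 1338 and 1175 CPM and germline genes 305, 409.9, 935, 1030 and 336 CPM.

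Some repeat families were far more abundant per gene UMI in Exit_1 than in the other classes of the library annotated 24 h, where total repeat counts per gene UMI were 1.61, 0.137 and 0.110. These families belong to no list fixed beforehand, apart from GSAT_MM, B1_Mm and MERVL-int, and no test compared them. B2_Mm1a, a short interspersed element, had 586132 counts on the CPM scale of gene UMIs in Exit_1, 26758 in Exit_2 and 17539 in Exit_3. GSAT_MM had 88005, 822 and 197, and MERVL-int 11235, 415 and 20.4. The family annotated 7SK, a small nuclear RNA, had 856, 9.91 and 6.46, and it reached 4935 in Exit_1 cells annotated 0 h. As a percent of all repeat counts, B2_Mm1a took 36.5% in Exit_1, 19.5% in Exit_2 and 16.0% in Exit_3, and GSAT_MM took 5.48%, 0.5996% and 0.179%. B1_Mm went the other way on that scale, at 0.607%, 1.45% and 1.85%. Between the libraries 7SK had the lowest ratio of all measured families, -7.24 per gene UMI and -3.40 per repeat count.

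A few Exit_3 cells annotated 24 h were rich in markers of other early lineages. In 1 cell with 23267 UMIs the trophectoderm list had 296 UMIs, of which 121 were Krt18, 97 Krt8 and 28 Peg10, and in another it had 102, against a median of 1 over all cells. The primitive endoderm list had 267, 206 and 134 UMIs in 3 other cells, led by Sparc with 114, 78 and 44, against a median of 4. The cells annotated 0 h are far shallower (median 1584.5 against 18591.5 UMIs), so absolute counts cannot be set side by side. Their highest counts were 6 and 12 UMIs, in cells with 33206 and 28123 UMIs.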
